A study of Caenorhabditis elegans with 4 samples.

How the data were processed

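Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of RNA polymerase II was carried out on late embryos of the wild-type *Caenorhabditis elegans* strain N2, the standard laboratory strain, from hermaphrodite cultures. Per the labels, the embryos were taken 4.5 hours after the early embryo stage at 20 °C. There were 4 libraries: 2 immunoprecipitated libraries (ChIP) and 2 libraries of input chromatin, numbered as replicates 1 and 2 in each group. Per the labels' protocols, embryos were fixed in formaldehyde (2%), the fixation was stopped with Tris (100 mM), and chromatin was sonicated, immunoprecipitated, size-selected on a gel and made into Illumina libraries. The sample labels name a mouse monoclonal antibody against the repeated C-terminal heptapeptide of the largest polymerase subunit, which ama-1 encodes. The shared protocol text speaks instead of serum against GFP, and the sample labels were followed. Nothing in the labels says whether the replicates came from separate cultures.

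The deposited table is a single list of regions for the series. Per the file headers, coordinates are on WormBase build WS180, and each row names PeakSeq, a caller that scores ChIP against input, as its source. The only value per region is the authors' q-value, a p-value corrected for multiple testing, which the attribute column repeats. The name of the list calls it combined, so it holds no value per library or per replicate, and how the replicates were joined is not given in the sources used here. The aligner, the caller's version and settings, the read filters and the depth of each library are also not given in the sources used here. A q-value depends on the number of reads as well as on enrichment, so wide regions reach smaller q-values at equal enrichment. No mean, SD or test between libraries could be computed. Each p-value below describes the placement or properties of regions within this list, and regions are not biological replicates.

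Widths, gaps and counts were computed from the 1-based start and end of each region. Chromosome lengths of WS180 were not used here, and each chromosome's span was taken as the end of its last region. Region counts per chromosome were tested against 10000 random rotations of all regions along the joined chromosomes, which keep their spacing, with Benjamini-Hochberg adjustment over the 6 chromosomes. Intervals of density ratios came from 10000 bootstrap resamples of 1-Mb blocks. The share of region midpoints in the middle 33.3% of a chromosome was tested with 10000 rotations within each chromosome. Width and −log10 of the authors' q-value were compared between X and autosomes by a permutation test of medians with 100000 resamples, with intervals from 2000 bootstrap resamples. Their relation across regions was given as Spearman and Pearson correlations with 100000 permutations and Benjamini-Hochberg adjustment. Nearest distances were compared with 1000 uniform placements that kept each chromosome's number of regions. All tests were two-sided, and intervals of shares are exact 95% binomial (Clopper-Pearson) intervals that cover counting error only. The smallest p that the rotations can give is 0.0002, and the smallest that the permutations can give is 1e-05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

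The rotation tests were tested on simulated data with 100 clustered lists of 5364 regions. With no difference built in, X was called in 8% of lists and the chromosome centres in 4%. Where the realised X density averaged 0.60 of the autosomal density, X was called in 54% of lists. Centres made 2 times as dense as arms were called in 100% of lists. The autosomes in the real list had smaller ratios of middle to outer density, from 1.13 on III to 1.35 on V. Detection at that size was not simulated. The simulated clusters were short, so these rates may not hold for density that varies over longer stretches.

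The reference gene table at hand is of assembly WBcel235, another build than WS180. It served only for the number of protein-coding genes per chromosome, and no region was assigned to a gene. The planned shares of regions by gene feature and the test of 27 gene lists were therefore not run, and the genes of the naming rule were not placed. The rule for what the text names was also set in advance: the 25 regions with the smallest q-value and the 3 widest regions. The densest windows, the longest gaps and the further X regions were chosen after seeing the data, as were the comparisons of width and q-value between X and autosomes, of X with each autosome, of X across q-value and width classes, of clustering, and of the centre shares between autosomes and X. Settings varied, as chosen before the data were examined, were the 50% of regions with the smallest q-values, merging of near regions, covered bases in place of counts, densities per gene and a wider centre, and, for the number of regions, a q-value of at most 0.001. Settings added after seeing the data were that q-value limit for densities and centres, leaving out regions under 100 bp, leaving out each autosome for the centres, covered bases per gene, and every setting for the difference in centre share.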

Results

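RNA polymerase II occupancy was mapped in late embryos of wild-type *C. elegans* by comparing 2 ChIP libraries with 2 input libraries. The stated aim was to identify the regions bound by the polymerase at this stage. The ChIP against input comparison was available as the authors' combined list of 5364 called regions, all with a q-value below 0.01 (the largest was 0.00998). The depth of the libraries was unknown, and the list gave no replicate spread.

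The called regions lay on all 6 nuclear chromosomes and covered 3.92 Mb, which was 3.92% of the 99.9 Mb spanned. Most were short: the median width was 430 bp, with an interquartile range of 216 to 813 bp. Broad regions were few but took up much of the occupied sequence. The 372 regions of 2000 bp or more were 6.94% of the list and held 34.8% of the covered bases, and the 63 regions of 5000 bp or more held 11.3%. At the other end, 521 regions (9.71%) were under 100 bp and together held 0.602% of the covered bases, down to a width of 1 bp. No regions overlapped, and the smallest gap between neighbours was 200 bp. The q-values ran from 1.55e-282 to the threshold with a median of 0.00015. A q-value of at most 0.001 was reached by 3515 regions (65.5%).

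Ranked by q-value, which favours wide regions at equal enrichment, the leading regions were mostly broad stretches, and every chromosome held at least 1 of them. Among the 25 regions with the smallest q-values, 7 were on chromosome II, 6 on I, 5 on IV, 3 on III, 3 on V and 1 on X, and their median width was 4645 bp. The smallest q-value, 1.55e-282, belonged to a 4862 bp region on chromosome II (14403404 to 14408265, all coordinates on WS180). The next was a 3494 bp region on X (12691487 to 12694980) with a q-value of 6.83e-253. A 12044 bp region on chromosome I (5302303 to 5314346) followed with a q-value of 4.15e-249. Chromosome II also held a 10902 bp region (10541841 to 10552742, q-value 6.19e-244) and a 4296 bp region (11633826 to 11638121, q-value 2.23e-236). On chromosome IV, a 10872 bp region (13026697 to 13037568) had a q-value of 1.33e-239 and a 3944 bp region (7485497 to 7489440) had a q-value of 9.04e-239. The leading region of chromosome V spanned 4019 bp (19519052 to 19523070, q-value 2.04e-219), and that of chromosome III spanned 11945 bp (9764659 to 9776603, q-value 9.54e-217).

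All 3 of the widest regions were among these 25. The widest spanned 12568 bp on chromosome IV (5977101 to 5989668, q-value 1.19e-180), followed by the regions of 12044 bp on I and 11945 bp on III. Only 1 of the 25 was under 1000 bp wide, a 987 bp region on chromosome II (5543361 to 5544347) with a q-value of 2.38e-178. The regions of the 25 not given here had q-values from 7.19e-234 to 5.06e-175.

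Broad regions had smaller q-values throughout the list. The median q-value was 0.00289 for regions under 100 bp, 0.000685 for those of 100 to below 500 bp, 5.44e-06 for 500 to below 1000 bp and 6.78e-10 for 1000 to below 2000 bp. It reached 1.59e-25 for 2000 to below 5000 bp and 8.63e-81 above that. Across the 5364 regions, which are not independent replicates, width and −log10 q-value correlated with a Spearman rho of 0.64 and a Pearson r of 0.41 on log10 width. Both had a permutation p of 1e-05, the smallest the permutations can give, and the same value after Benjamini-Hochberg adjustment over the 8 correlations computed. A relation of this sign is built into a q-value that depends on the number of reads. It does not show that broad regions were more enriched.

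**Figure D1:**
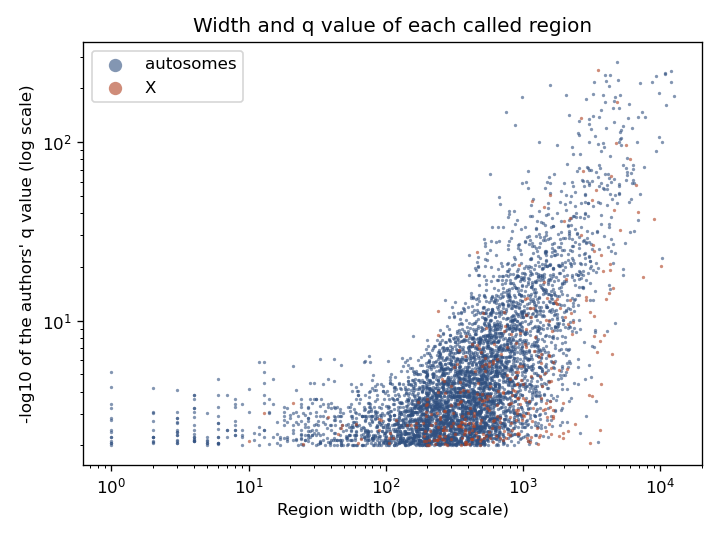
Each point is 1 called region, with its width in bp on the horizontal log axis and −log10 of the authors' q-value on the vertical log axis, autosomal regions in blue and X regions in red. Most regions under 100 bp (72.2%) have a q-value above 0.001, and the regions with the smallest q-values are mostly wider than 1000 bp (median width 4645 bp for the 25 smallest).

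The polymerase was called far less often on the X chromosome than on the autosomes. X carried 346 regions, or 6.45% of the list (exact 95% interval 5.81 to 7.14%), on 17.6% of the spanned sequence. This was 19.7 regions per Mb against 60.96 on the 5 autosomes together, a ratio of 0.322 (95% block bootstrap interval 0.275 to 0.378). In the rotation permutation test p was 0.0002, the smallest that the rotations can give (adjusted p = 0.0012). With 6 chromosomes, however, an exact test of 1 chromosome label against 5 cannot go below 0.167.

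X regions were fewer but wider. Their median width was 674 bp against 417.5 bp on the autosomes, a difference of 256.5 bp (bootstrap interval 144 to 391 bp, permutation p = 1e-05, adjusted p = 2e-05). Single autosomes had medians from 358 bp on I to 530.5 bp on V. The median −log10 q-value of X regions was lower by 0.43 (interval of the difference −0.77 to −0.16, permutation p = 0.023, adjusted p = 0.023). Both permutation tests treat regions as independent units, and the q-value threshold shapes which widths enter the list. X supplied 2.69% of the regions under 100 bp, 4.89% of those of 100 to below 500 bp, 6.64% of those of 500 to below 1000 bp, 10.8% of those of 1000 to below 2000 bp and 14.2% of those of 2000 to below 5000 bp. Among the 63 regions of 5000 bp or more it supplied 8, or 12.7%. The share of span covered was 2.29% on X and 4.27% on the autosomes, so the ratio by covered bases, 0.535 (interval 0.441 to 0.631), was closer to 1 than the ratio by number. The X regions with the next smallest q-values after the one named above lay at 4960217 to 4965075 (q-value 9.40e-169) and at 13143128 to 13145759 (q-value 2.89e-136).

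The size of the X deficit depended on the autosome and on the measure. X has fewer protein-coding genes per Mb (155 against 209 in the WBcel235 gene table), and it carried 12.7 regions per 100 such genes against 29.1 on the autosomes, a ratio of 0.435 (interval 0.371 to 0.510). Chromosome V came closest to X, with 16.3 regions per 100 genes, for a ratio of X to V of 0.780 (interval 0.622 to 0.989). In covered bases per gene, X held 147 bp against 204 bp on the autosomes (ratio 0.723, interval 0.598 to 0.849). By that measure X and V, at 147 and 143 bp, did not differ beyond the interval of their ratio, 0.804 to 1.33.

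**Figure D2:**
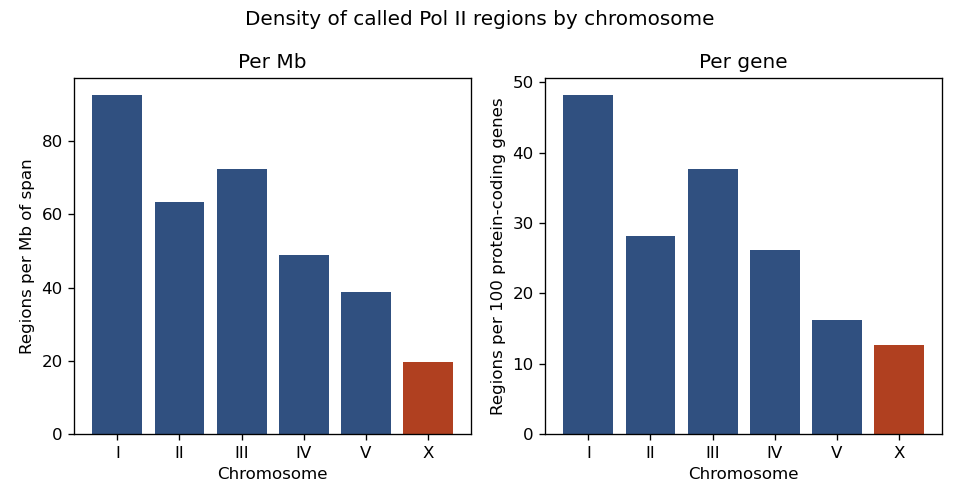
Bars give called regions per Mb of span (left) and per 100 protein-coding genes (right) for each chromosome, autosomes in blue and X in red, for 1 combined list without replicate error. Chromosome I is highest at 92.5 per Mb and 48.14 per 100 genes, and X is lowest at 19.7 per Mb and 12.7 per 100 genes.

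Chromosome I stood out in the other direction. It held 1385 regions, 25.8% of the list (exact 95% interval 24.7 to 27.01%) on 14.98% of the span, or 92.5 per Mb, and exceeded the rotations (rotation permutation test, adjusted p = 0.027). Here too, an exact test of 1 chromosome label against 5 cannot go below 0.167. Its regions were the narrowest by median (358 bp), so its lead was smaller by covered bases. They covered 5.44% of its span, against 4.55% on III and 4.44% on II, a contrast given without a test. The counts on III (72.3 per Mb), II (63.4 per Mb), IV (49.0 per Mb) and V (38.9 per Mb) did not differ from the rotations, with adjusted p between 0.708 and 0.930.

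Within chromosomes, autosomal regions were moderately concentrated in the centres, which in this species are the gene-rich parts with little recombination. Of 5018 autosomal regions, 1877 had their midpoint in the middle 33.3% of their chromosome, or 37.4% (exact 95% interval 36.1 to 38.8%), which is 1.12 times an even spread. Rotations within chromosomes gave 33.3% on average, with 95% of them between 29.9 and 36.8% (rotation permutation test, unadjusted p = 0.0196). Without chromosome I the excess was 1.13 times (rotation permutation p = 0.0684) and without V 1.11 times (rotation permutation p = 0.0690), so the size of the excess changed little while the call was lost. No chromosome passed alone (adjusted p between 0.622 and 0.751). On X the middle part held 103 of 346 regions, or 29.8% (exact 95% interval 24.998 to 34.9%), which did not differ from the rotations (p = 0.427). The difference between autosomes and X, 7.64 percentage points, had a rotation permutation p of 0.0376, unadjusted, in a test added after the shares were seen. By covered bases the difference was 4.74 points and did not pass (rotation permutation p = 0.359), and the middle part of X lay at 1.04 times an even spread. The difference also did not pass for the 50% of regions with the smallest q-values (rotation permutation p = 0.262), without chromosome I (rotation permutation p = 0.0696) or without V (rotation permutation p = 0.0744).

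With each chromosome cut into 3 parts of equal length, chromosome I held 86.6, 103 and 88.0 regions per Mb from left to right and III held 69.9, 78.4 and 68.6. Chromosome V went from 32.4 regions per Mb in the left part to 47.1 in the middle and 37.4 in the right, and chromosome IV from 56.2 and 53.9 to 36.9. Chromosome II had 49.1 in the left part, against 71.1 in the middle and 70.1 in the right. On X the parts held 22.5, 17.6 and 18.9 regions per Mb. Differences between these profiles were not tested.

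**Figure D3:**
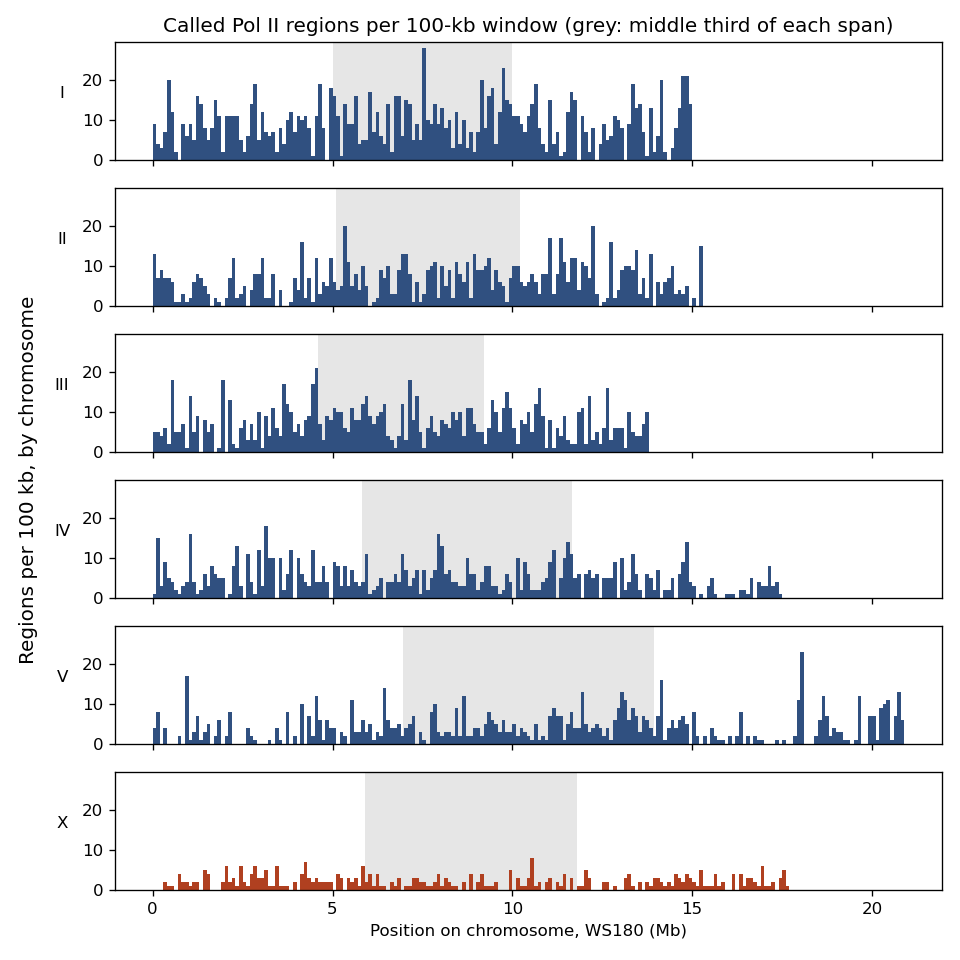
Bars count called regions in consecutive 100-kb windows along each chromosome (position in Mb on WS180), with the middle 33.3% of each span shaded and X in red. The fullest window, on chromosome I, holds 28 regions, whereas no X window holds more than 8.

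Called regions were clustered. The median distance from a region's midpoint to the nearest other midpoint was 1898.5 bp, against 5692 bp on average over 1000 uniform placements, 95% of which lay between 5422 and 5944 bp. Another midpoint lay within 2000 bp for 51.7% of regions, against 22.2% after placement. Merging neighbours closer than 500 or 1000 bp left 4247 or 3613 regions, so many near neighbours may be pieces of the same stretch. The distances and the window counts are for regions as listed, before any merging. The fullest 100-kb window was on chromosome I (7500001 to 7600000), with 28 regions covering 17.4 kb. It was followed by another on I (9700001 to 9800000) and by one on the outer right part of V (18000001 to 18100000), with 23 regions each. Of 1002 windows, 11.9% held no region. These were 20.9% of the X windows and 20.1% of the V windows, but 2.17% of those on III and 4% of those on I. The longest stretches without a region were 449.6 kb on V (2197546 to 2647145) and 443 kb on X (1521788 to 1965028).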

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

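Alternatives that left out short regions, applied the q-value limit to densities or centres, left out an autosome or counted covered bases per gene were chosen after seeing the data, as were all those for the difference in centre share. The number of regions fell from 5364 to 2682 for the 50% with the smallest q-values and to 3515 at a q-value of at most 0.001, and merging neighbours closer than 500 or 1000 bp left 4247 or 3613. X stayed below the autosomes in all 7 alternatives, with ratios from 0.273 (smallest 50% of q-values) to 0.723 (covered bases per gene). The autosomal centre excess stayed above 1 in all 10 alternatives, but without chromosome I (1.13) or without V (1.11) it no longer passed the test; the cause was not tested. The difference in centre share between autosomes and X stayed positive in all 10 alternatives (4.74 to 11.1 points) and passed in 6; it did not pass for the smallest 50% of q-values (7.92 points), by covered bases (4.74), without chromosome I (7.75) or without V (7.08), and the cause was not tested. The X centre share, not significant at 0.893 times an even spread, turned to 1.04 times by covered bases; the cause was not tested. The correlation of width with −log10 q-value kept its sign in all 3 alternatives (0.59 to 0.65). No paired analysis was possible because the list combines both replicates and holds no value per library, and for the same reason no replicate could be left out. Other windows and overlaps for gene features and gene lists were not run, since no gene map of the regions' build was used. Without library depths, regions below the threshold cannot be told from unoccupied sequence.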

Other observations

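The tests of short regions near the threshold and of matching counts were chosen after the results were seen, as were the comparisons of tag ratios below. The q-values carried more information than the list states. Where a q-value was followed by a smaller one, tied p-values gave a whole-number rank in 1889 of 2064 cases (within 0.001 of a whole number), and in 1887 of these the rank was 6 above the position in the list. With that offset and a total of 19306 tested candidates, each of the 5364 p-values equalled the upper tail of a binomial distribution with probability 0.5 for exactly 1 pair of whole counts, within 3e-09 on the natural log scale. At 20 neighbouring totals at most 0.149% of regions matched, which argues against coincidental matches. On a simulated list of 4871 regions, built with the same formula, the procedure returned both counts for 99.96%. That checks the procedure only and says nothing of what the counts in the real list are. The larger count may therefore be read as ChIP tags of both replicates together and the remainder as scaled input tags, as a hypothesis that the labels do not state, so the library depths stay unknown and no counting intervals are given for single regions. The offset would mean that 6 candidates rank above the regions analysed here; those 6 were not analysed here.

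Read in this way, the regions held 929246 ChIP tags against 418026 input tags, and the median ratio of ChIP to input was 2.23 (interquartile range 1.86 to 2.80). Ratios were modest for most regions, and 339 regions reached 4 or more. The highest ratio among regions with at least 100 ChIP tags was 14.5 in a 575 bp region on chromosome V (9088681 to 9089255), with 319 against 22 tags. Next came the 987 bp region on II (5543361 to 5544347), at 10.3, and a 753 bp region on II (5844614 to 5845366), at 8.78. The 12568 bp region on IV, the widest, had 3232 against 1315 tags, a ratio of 2.46. Regions with few tags pass the q-value threshold only at a high ratio, so the relation of ratio to width in this list is shaped by the threshold and was not interpreted. Only 3 of the 10 regions with the highest such ratios were among the 25 with the smallest q-values.

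The X regions in the list had lower ratios than the autosomal regions. Over all widths, which differ between them, the median was 1.84 on X and 2.26 on the autosomes (quotient 0.814, bootstrap interval 0.791 to 0.844, permutation p = 5e-05, the smallest that 20000 permutations can give). In the class of 500 to below 1000 bp it was 1.75 for 86 X regions and 2.06 for 1210 autosomal regions, and X was lower in all 4 classes tested from 100 to below 5000 bp (adjusted p between 0.0002 and 0.00065). Over all widths, single autosomes had medians from 2.12 on V to 2.38 on I, a spread the interval leaves out. These tests and the interval treat regions as independent units, although regions cluster. An exact test of 1 chromosome label against 5 cannot go below 0.167. In regions of 500 bp or more, scaled input tags per kb were 1.14 times as high on X (interval 1.10 to 1.17), and the input scaling is unknown. A lower ratio therefore need not mean fewer ChIP tags on X. The threshold decides which ratios enter the list, so the difference describes called regions only.

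The deficit of regions on X was set against 3 explanations. If X had fewer regions only because X carries fewer protein-coding genes, regions per gene on X would match those on the autosomes. The pooled ratio was 0.435 (interval 0.371 to 0.510), and by covered bases per gene it was 0.723 (0.598 to 0.849). The autosomes themselves differed, from 16.3 regions per 100 genes on V to 48.14 on I, a spread these intervals leave out. Against V alone the ratio was 0.780 by regions and 1.03 by covered bases. The interval of the pooled ratio by regions lay below the bound set in advance against this explanation. X was lowest by regions per gene, but that bound assumes equality, which fails among the autosomes too, so this test cannot decide. The cultures were of hermaphrodites, and nothing in the design points to a lower X DNA dose. Input tags per kb in regions of 500 bp or more had a ratio of 1.14 (interval 1.10 to 1.17), which cannot test it. The bound set for this test was wrong, since input is known only inside called regions and after an unknown scaling. It stays open whether X regions were too weak for the detection limit. X was 6.19% of the 1341 regions with the smallest q-values and 8.05% of the 1341 with the largest. The difference was −1.86 percentage points, and the exact intervals overlap (4.96 to 7.62% and 6.65 to 9.64%). Between them X was 4.85% of the next 1341 (3.76 to 6.14%, below the interval of the last) and 6.71% of those after. The share thus did not change steadily with q-value. These shares cannot decide the question, since q-values fall with width and X regions were wider. Within width classes X regions had the lower ratios, which describes called regions only. Lower transcription of X in hermaphrodites, through dosage compensation or through the kinds of genes X carries, may also contribute and was not tested, since the design has no contrast for it.

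The 521 regions under 100 bp are narrower than sonicated fragments usually are, and a candidate explanation is that they are tips of stretches that barely crossed the caller's threshold. Of these, 72.2% had a q-value above 0.001 against 30.4% of wider regions, a difference of 41.8 percentage points. This decides nothing, since a median of 33 ChIP and 11 input tags keeps most of their q-values near the threshold. Whether they are broken edges of wider regions also stays open: 20.2% lay within 1000 bp of a region of 500 bp or more, against 23.4% of the regions of 100 to below 500 bp, a difference of −3.26 percentage points with overlapping exact intervals.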
